A study of Homo sapiens with 6 samples.

How the data were processed

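Poly(A)-selected RNA from HCT116 cells, an established human colorectal carcinoma line, was sequenced in 6 libraries. The labels place 3 libraries in a control group (shCtrl) and 3 in a PRSS22 knockdown group (shPRSS22). The series' design text calls the control cells wild type, whereas the sample titles name them shCtrl; nothing in the labels gives the hairpin sequence, the time after its introduction or whether replicates came from separate cultures. Per the labels' protocols, mRNA was captured on oligo(dT) beads, fragmented, copied with random primers and sequenced from circularised single-stranded DNA. No strand marking is described, so reads from a gene and an overlapping antisense gene were treated as not separable.

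The authors deposited 1 table of 17269 genes with Entrez identifiers and symbols. Per the submitters' processing notes, FastQC 0.12.1, HISAT2 2.2.1, Bowtie2 2.3.4.3, RSEM 1.3.1, DESeq2 1.4.5 and R 4.3.1 were used with genome build GRCh38.p13; the notes do not give their roles or order. Per the file headers, the table holds a read count, an FPKM, a TPM and a normalised read count for each library. The deposited read counts are estimated counts: between 2081 and 2162 genes per library carried decimals, and those genes held 13.9% to 15.2% of the counts. Estimated counts divide reads shared by near-identical genes among them, so paralogs and genes with expressed pseudogenes are less certain. The deposited FPKM and TPM values were not used for any result. The deposited normalised read counts, a scaled signal, equalled the rounded counts times 1 factor per library, between 0.980 and 1.02, and were not used either. The table also gives the authors' comparison as a log2 fold change, a p-value and a q-value per gene, per the file headers; 16977 genes had a p-value. The deposited q-values equalled the Benjamini-Hochberg adjustment of the deposited p-values.

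For the present text the estimated counts were rounded to whole numbers. Library totals were 14920523, 15164328 and 15121770 counts for shCtrl replicates 1 to 3 and 15466647, 15363080 and 15332449 for shPRSS22 replicates 1 to 3. A count was present for 15374 to 15615 genes per library, 287 genes had none in any library, and the 10 most abundant genes took 7.69% to 8.11% of the counts. Replicates were compared by a chi-square statistic over genes with more than 20 counts in a pair. It was 1.80 to 1.85 per gene among shCtrl pairs and 2.15 to 3.05 among shPRSS22 pairs, where sampling alone leaves about 1. Such an excess does not tell separate cultures from technical repeats. Each library was counted as 1 replicate. In the main test described below, the common coefficient of variation between libraries of a group, beyond counting noise, was 2.97%. The labels do not say that replicates were separate cultures; p-values then measure only the spread between these samples, which may be technical.

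The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3; robust glmQLFit and glmQLFTest) with TMM scaling and filterByExpr, which left 13104 genes. Adjusted p-values are Benjamini-Hochberg values over these genes, tests are two-sided, and the threshold was 0.05. Levels are CPM, the count per 1000000 of the library's TMM-scaled total over the tested genes, given as mean ± SD over 3 libraries. A limit of 0.5 CPM set for marker genes used the unscaled total of all genes. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Fold changes are shPRSS22 against shCtrl.

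Lists of genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, where at least 5 members were tested, with adjustment over the 19 lists that qualified among 24. Camera asks whether a list moves relative to all other genes. The same test with an estimated correlation, and fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. The lists cover p53, mitosis, DNA replication, Wnt, ERK, immediate early, YAP, mesenchymal, epithelial, pericellular proteolysis, NF-kB, interferon, ATF4, endoplasmic reticulum chaperone, NRF2, hypoxia and glycolysis, cholesterol, ribosomal protein, oxidative phosphorylation, intestinal differentiation, mitochondrially encoded, histone, fibroblast with immune and endothelial, and trypsin-like protease genes. The genes BTG2, CCND1, COL1A1, COL1A2, COL3A1, PRSS8 and SLC7A11 stand in 2 lists each. Mitochondrially encoded genes were not analysed here.

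Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes PRSS22; the 8 highest and 8 lowest fold changes among genes past the threshold with a mean CPM of at least 5 and no overlap between groups; up to 2 members with the largest rise and 2 with the largest fall in each list, at a mean CPM of at least 1; and the 2 smallest p-values per direction. Other members are named where they describe a list, and were chosen after their values were seen; not every gene that the rule takes is reported here.

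Alternatives were RLE scaling, total count scaling, no filter, a mean CPM of at least 1, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, and for lists an estimated correlation, fry and lists without shared members, the last chosen after seeing the data. The test was tried on simulated data for this comparison with 13104 genes. It recovered 98 of 100 genes changed by 2-fold and 72 of 100 changed by 0.32 on the log2 scale, and called 24 of 12904 unchanged genes. On these simulated data camera called the 1 shifted list and 0 of the 18 others. Entrez identifiers matched the RefSeq gene table of assembly GRCh38.p14 for 17215 of 17269 genes. Coordinates, transcript lengths and 3' UTRs came from GENCODE release 29 on GRCh38. Sequence and marker counts used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.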

Results

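The transcriptome of HCT116 cells, a human colorectal carcinoma line, was measured by poly(A) RNA sequencing in 3 control libraries (shCtrl) and 3 libraries of cells in which PRSS22 was knocked down with a short hairpin RNA (shPRSS22). The comparison asks which transcripts differ when PRSS22 is depleted. Each library held between 14920523 and 15466647 estimated counts.

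PRSS22, which encodes a secreted trypsin-like serine protease, was lower in every knockdown library. Its level was 10.1, 9.38 and 10.1 CPM in shCtrl replicates 1 to 3 and 3.09, 3.16 and 2.61 CPM in shPRSS22 replicates 1 to 3. The group means were 9.86 ± 0.416 and 2.95 ± 0.296 CPM (SD, n = 3). The log2 fold change was -1.74 (SE 0.135; edgeR quasi-likelihood test, adjusted p = 4.78e-12). The authors' deposited table also gives -1.74. The gene (Entrez 64063) lies on chromosome 16 from 2852727 to 2858170 on the minus strand of GRCh38, with 6 exons, a transcript of 1386 bases and a 3' UTR of 366 bases. Of its trypsin-like relatives with enough counts, PRSS27 had a log2 fold change of -0.76 and PRSS8 one of -0.07, and neither passed the threshold over all genes. Adjusted over the list alone, PRSS22 and PRSS27 were lower, 2 of 3 tested members. PRSS27 had a mean of only 0.965 CPM over all libraries (SE of its log2 fold change 0.321), a level of few counts.

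COL6A3, the alpha-3 chain of collagen VI, rose most among well-measured genes. It went from 2.56 ± 0.244 to 10.4 ± 0.597 CPM, a log2 fold change of 2.02 (SE 0.138). SPP1, which encodes osteopontin, rose by 1.70 on the log2 scale, INHBE, an inhibin beta subunit, by 1.56, and MMP1, interstitial collagenase, by 1.36. DKK1, a secreted inhibitor of Wnt signalling, rose from 36.5 ± 7.35 to 102 ± 17.9 CPM (log2 fold change 1.49, SE 0.221, adjusted p = 0.00804). OSGIN1, an oxidative stress response gene, rose by 1.48, GRAMD1B, a sterol transfer protein of the endoplasmic reticulum, by 1.38, and TRIM16L by 1.46. TRIM16L resembles TRIM16 closely, so reads may have been divided between them. The smallest p-values belonged to TXNRD1, cytosolic thioredoxin reductase, at 537 ± 8.35 against 1288 ± 50.7 CPM (log2 fold change 1.26, adjusted p = 4.91e-23), and SRXN1, sulfiredoxin, at 307.4 ± 3.29 against 664 ± 27.7 CPM (1.11).

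The largest fall among well-measured genes was that of PRSS22 itself. CTHRC1, a secreted collagen triple helix repeat protein, had a log2 fold change of -1.37, ADAMTS14, a procollagen N-proteinase, one of -1.18, and the growth factor FGF9 one of -1.18. CHPF, a chondroitin polymerising factor, went from 313.8 ± 3.04 to 158.5 ± 7.23 CPM (log2 fold change -0.98, adjusted p = 2.08e-20). LTBP3, a latent TGF-beta binding protein, went from 184.7 ± 5.12 to 93.8 ± 6.25 CPM (-0.98). The transporter SLC16A6 (-1.36), the pannexin PANX2 (-1.05) and PAAF1, a proteasomal ATPase associated factor (-1.03), also fell.

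Across the transcriptome, 2603 genes were higher and 2523 lower in shPRSS22 among 13104 tested, at adjusted p under 0.05. Most changes were small: the median fold among these genes was 1.19, and 4651 of them (90.7%) changed by under 1.5-fold. By at least 2-fold, 95 genes were higher and 30 lower. The groups did not overlap for 6364 genes, 48.6% of those tested, where chance gives 10%. The authors' deposited table lists 1645 genes higher and 1510 lower at a q-value under 0.05, of which 1630 and 1498 were also called here in the same direction. DESeq2 called 1760 higher and 1637 lower. Genes lower by at least 2-fold numbered 53 without shPRSS22 replicate 1, and with no filter on low counts 160 were higher and 64 lower by at least 2-fold. The 2-fold counts were 64 and 23 at a mean CPM of at least 1, 64 and 20 with DESeq2 and 78 and 25 in the authors' table.

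**Figure D1:**
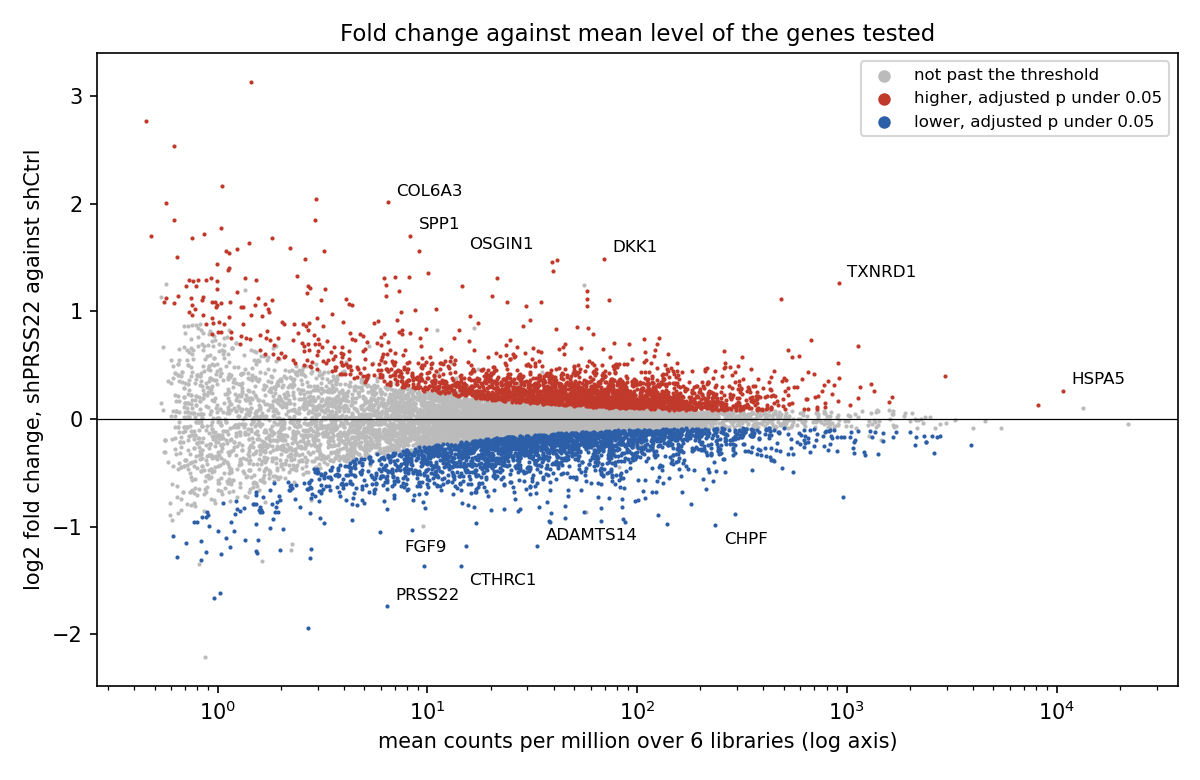
Log2 fold change of shPRSS22 against shCtrl (vertical axis) by mean CPM over 6 libraries (horizontal log axis), 1 point per tested gene. Red points are the 2603 higher genes, blue points the 2523 lower genes and grey points the rest of the 13104 tested; PRSS22 stands at -1.74 and COL6A3 at 2.02.

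**Figure D2:**
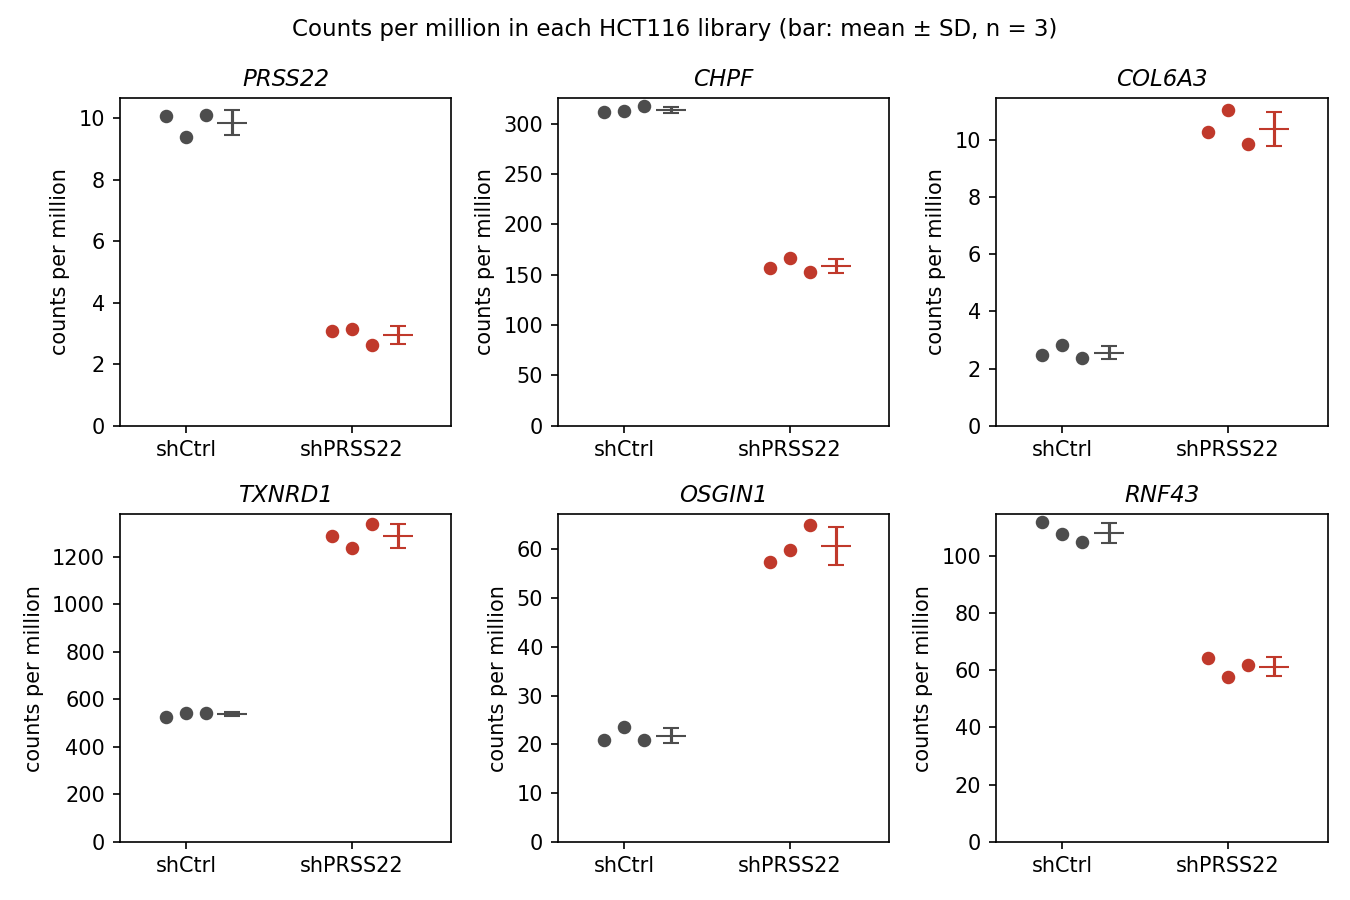
Level in CPM (vertical axes, from 0) of 6 genes in each shCtrl (grey) and shPRSS22 (red) library, with 1 point per library and the mean ± SD of 3 libraries beside them. PRSS22, CHPF and RNF43 are lower in all 3 shPRSS22 libraries, and COL6A3, TXNRD1 and OSGIN1 are higher in all 3.

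The NRF2 target list, genes of the antioxidant response, moved furthest of the lists tested. Of 20 tested members 18 rose and 0 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 0.71 (camera, adjusted p = 6.03e-60). Besides TXNRD1, SRXN1 and OSGIN1, the members that rose included GCLM (1.11) and GCLC (0.47), which form the rate-limiting enzyme of glutathione synthesis, and HMOX1 (1.05), heme oxygenase 1. The ferritin chains FTL (0.68) and FTH1 (0.40), both with many pseudogenes, rose, as did the NADPH-producing malic enzyme ME1 (0.75) and the cystine transporter SLC7A11 (0.58). AKR1C3, an aldo-keto reductase with near-identical paralogs, rose by 1.32. NQO1, a quinone reductase often used as a reporter of this response, rose by only 0.19, and the values of AKR1C1 (0.26) and UGDH (0.07) did not pass the threshold. The list kept its call with an estimated correlation (adjusted p = 0.0186).

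Genes of the ATF4 amino acid response also rose. Of 24 tested members 20 were higher and 1 lower, over all genes and adjusted over the list alone, with a median of 0.22 (camera, adjusted p = 1.67e-13; 0.0186 with an estimated correlation). CHAC1, which degrades glutathione, rose from 94.5 ± 1.37 to 153.4 ± 1.81 CPM (log2 fold change 0.70), the transcription factor DDIT3 by 0.52 and the serine synthesis enzyme PSAT1 by 0.38. ATF5, a transcription factor of the same response, was the exception, falling from 29.8 ± 1.22 to 16.7 ± 1.86 CPM (-0.84). Endoplasmic reticulum chaperone genes did not move together: 5 of 20 rose, 6 fell and 9 did not pass, against 5 and 7 adjusted over the list alone (camera, adjusted p = 0.854). HERPUD1 (0.30), a factor in degradation of misfolded proteins, and the chaperone HSPA5 (0.26) rose, while CRELD2 (-0.34) and the chaperone HYOU1 (-0.32) fell.

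Cholesterol synthesis genes rose in 13 of 23 tested members and fell in 1, or 15 and 1 adjusted over the list alone. Their median log2 fold change was 0.22 (camera, adjusted p = 8.45e-07; 0.0274 with an estimated correlation). INSIG1, a sterol-regulated anchor of SREBP processing, rose by 0.69 and the sterol desaturase SC5D by 0.52, whereas the sterol reductase TM7SF2 fell (-0.42).

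Target genes of p53, which is wild type in HCT116 cells, rose in 12 of 24 tested members and fell in 2, or 13 and 2 adjusted over the list alone (median 0.13; camera, adjusted p = 5.31e-05). The list's call was lost with an estimated correlation (adjusted p = 0.0626 with an estimated correlation). The secreted factor GDF15 rose from 409.7 ± 3.39 to 638.0 ± 4.14 CPM (log2 fold change 0.64), PHLDA3, an inhibitor of AKT, by 0.59, the cell cycle inhibitor CDKN1A by 0.47 and the p53 ubiquitin ligase MDM2 by 0.12. BTG2, an antiproliferative gene (-0.37), and FDXR, a mitochondrial reductase (-0.35), fell.

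Mitosis and G2/M genes rose in 7 of 25 tested members and fell in 0, or 6 and 0 adjusted over the list alone. The kinetochore gene NDC80 (0.68), the kinase AURKB (0.53) and the spindle factor TPX2 (0.35) rose. The list's median was 0.33 (camera, adjusted p = 0.0375; adjusted p = 0.963 with an estimated correlation and 0.364 in fry). Its mean log2 level, relative to the mean of the 6 libraries, was 0.36 and 0.34 in shPRSS22 replicates 1 and 2 but -0.26 in replicate 3, and it was -0.11, -0.0087 and -0.32 in shCtrl replicates 1 to 3. The call was lost without shCtrl replicate 3 (adjusted p = 0.181), without shPRSS22 replicate 1 (0.212) and without shPRSS22 replicate 2 (0.194). AURKB alone lost its call without shCtrl replicate 3 (log2 fold change 0.495, adjusted p = 0.0648) and without shPRSS22 replicate 1 (0.315, adjusted p = 0.225). In the DNA replication list 1 of 25 rose and 6 fell, over all genes and adjusted over the list alone (camera, adjusted p = 0.454): CCNE1, cyclin E1, rose by 0.41, and the replicative helicase genes GINS2 (-0.53) and MCM2 (-0.42) fell. The replication list's mean log2 level was 0.080 and 0.056 in shPRSS22 replicates 1 and 2 but -0.235 in replicate 3, against 0.052, 0.076 and -0.028 in shCtrl replicates 1 to 3.

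Interferon-stimulated genes were lower as a list. Of 20 tested members 12 fell and 0 rose, over all genes and adjusted over the list alone, with a median of -0.33 (camera, adjusted p = 5.31e-05; 0.0429 with an estimated correlation). OAS3, a double-stranded RNA sensor, went from 32.8 ± 1.18 to 19.5 ± 2.10 CPM (log2 fold change -0.75), the ubiquitin-like protein ISG15 changed by -0.70 and the transcription factor IRF9 by -0.52. IFI27 fell from 2.17 ± 0.104 to 0.912 ± 0.472 CPM (-1.24), a level of few counts.

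Target genes of NF-kB fell in 7 of 17 tested members and rose in 2, over all genes and adjusted over the list alone (median -0.22; camera, adjusted p = 0.0161; adjusted p = 0.118 with an estimated correlation). The chemokines CCL20, at 1.55 ± 0.176 against 0.501 ± 0.313 CPM (-1.62), and CXCL1 (-0.69) fell, as did BIRC3, an inhibitor of apoptosis (-0.69). The cytokine IL1A (0.69) and TNFAIP2 (0.17) rose. IL1A lost its call without shCtrl replicate 1 (adjusted p = 0.0533) and without shCtrl replicate 3 (0.0712).

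Wnt/beta-catenin target genes fell in 7 of 15 tested members and rose in 1, over all genes and adjusted over the list alone (median -0.23; camera, adjusted p = 7.56e-04; adjusted p = 0.0626 with an estimated correlation). The members that fell included the feedback inhibitors RNF43, from 108.0 ± 3.54 to 61.2 ± 3.31 CPM (-0.82), NKD1 (-0.72) and AXIN2 (-0.54), and the transcription factor SOX9 (-0.49). DKK1 was the member that rose, while MYC, at 0.07, did not pass the threshold. With the replicate number as a block the list's call was lost (camera, adjusted p = 0.0544).

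Cytosolic ribosomal protein genes fell in 11 of 30 tested members and rose in 0, over all genes and adjusted over the list alone, by small amounts (median -0.07; camera, adjusted p = 0.00585; adjusted p = 0.963 with an estimated correlation and 0.246 in fry). The list's mean log2 level, relative to the mean of the 6 libraries, was -0.072 and -0.087 in shPRSS22 replicates 1 and 3 but 0.034 in replicate 2, within the shCtrl values of 0.017, 0.074 and 0.033. RPS2 (-0.31) and RPS9 (-0.28) fell most.

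**Figure D3:**
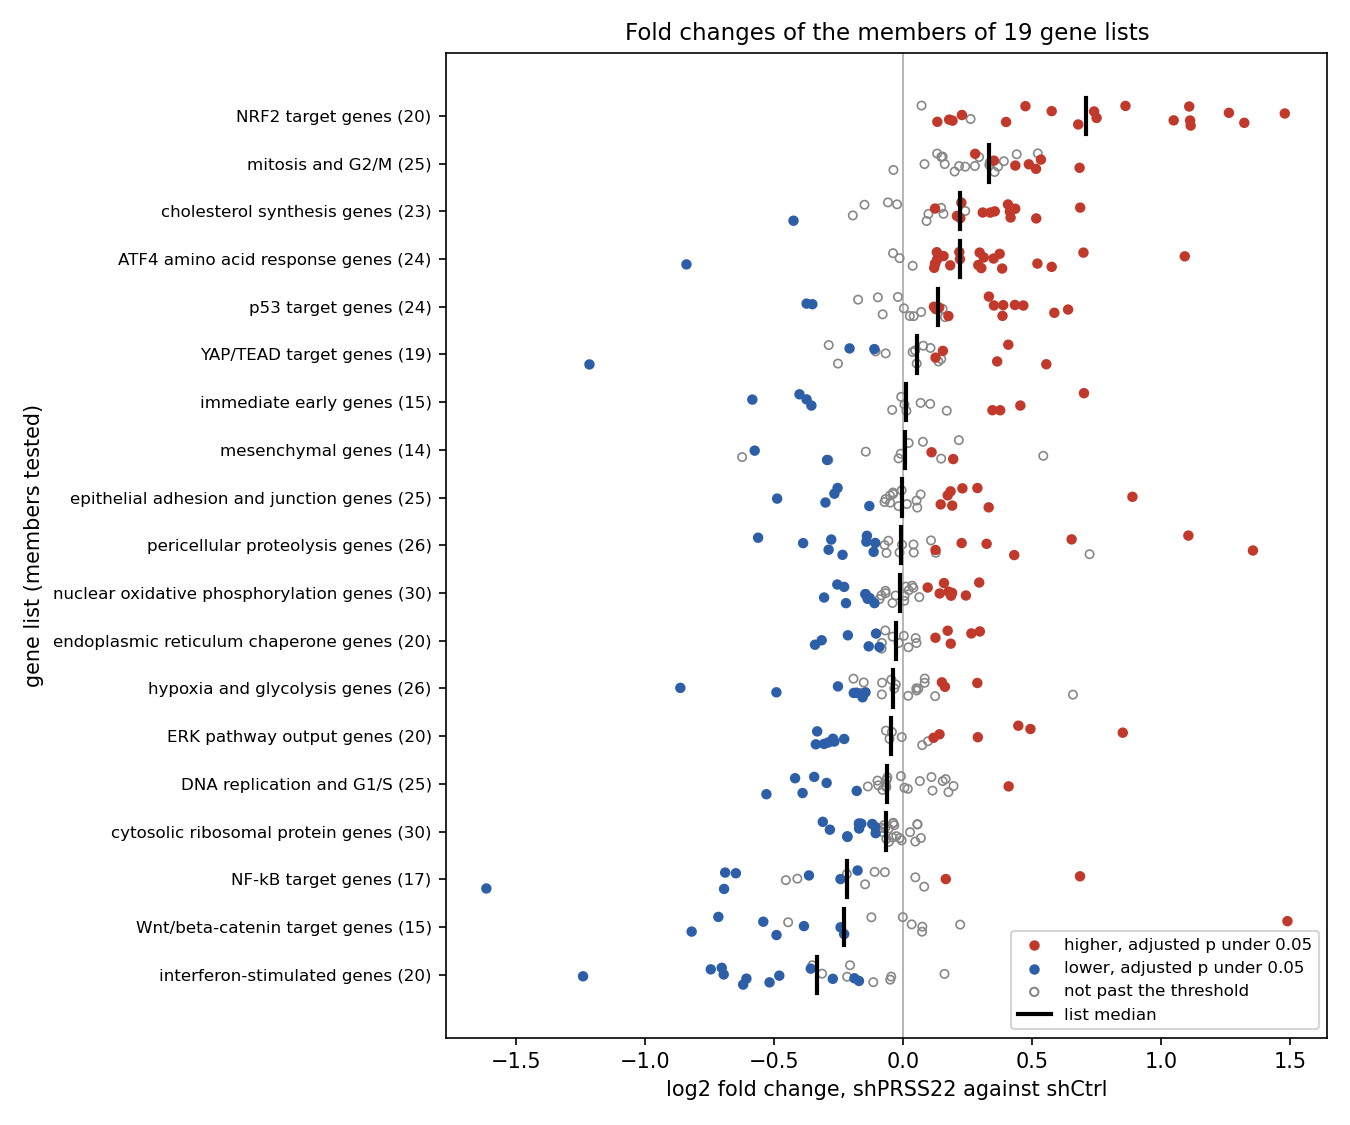
Log2 fold change of shPRSS22 against shCtrl (horizontal axis) for the tested members of 19 gene lists (vertical axis, number tested in parentheses), 1 point per gene. Filled points passed an adjusted p of 0.05 and black bars are list medians, from -0.33 for interferon-stimulated genes to 0.71 for NRF2 target genes.

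Lists of signalling output and cell state held members that moved both ways, and camera called none of the following. Among ERK output genes 6 of 20 rose and 8 fell (adjusted p = 0.875): the AP-1 subunit FOSL1 (0.85) and the receptor EPHA2 (0.49) rose, and the EGFR ligand EREG (-0.34) and the receptor EPHA4 (-0.33) fell. Among immediate early genes 4 of 15 rose and 4 fell (0.854): the stress factor ATF3 rose by 0.70 and FOSB by 0.45, and KLF2 (-0.58) and EGR2 (-0.40) fell. FOSB lost its call without shCtrl replicate 1 (adjusted p = 0.0707), shCtrl replicate 3 (0.0860), shPRSS22 replicate 1 (0.105) or shPRSS22 replicate 2 (0.0867). YAP/TEAD target genes rose in 5 of 19 members and fell in 3 (0.454), with CCN2 (0.55) and AJUBA (0.41) higher and TGFB2 (-1.22, at 1.99 CPM on average) and AMOTL1 (-0.21) lower.

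Adhesion and protease lists were equally mixed. Mesenchymal genes rose in 2 of 14 and fell in 2 (adjusted p = 0.922): the integrin ITGA5 (0.19) and fibronectin, FN1 (0.11), rose, and SPARC (-0.58) and the repressor ZEB1 (-0.29) fell. FN1 lost its call without shCtrl replicate 1 (0.108), shCtrl replicate 2 (0.0628) or shPRSS22 replicate 3 (0.0673), and ZEB1 without shCtrl replicate 1 (0.171), shCtrl replicate 3 (0.156), shPRSS22 replicate 1 (0.102) or shPRSS22 replicate 2 (0.15). Epithelial junction genes rose in 8 of 25 and fell in 5 (0.785), with claudin 1, CLDN1 (0.89), and the transcription factor ELF3 (0.33) higher and CLDN3 (-0.49) and desmoplakin, DSP (-0.30), lower. Pericellular proteolysis genes rose in 7 of 26 and fell in 9 (0.922): besides MMP1, the serpin SERPINB5 rose by 0.65, while the urokinase receptor PLAUR (-0.56) fell. All of these counts were the same adjusted over the list alone. The median and mean differed in sign for ERK output (-0.048 and 0.0014), YAP/TEAD (0.052 and -0.0022), mesenchymal (0.0059 and -0.046), epithelial (-0.0058 and 0.033) and pericellular proteolysis genes (-0.0092 and 0.107), and camera's direction was down for ERK output and pericellular proteolysis and up for the others.

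Energy metabolism lists were not called either. Hypoxia and glycolysis genes rose in 3 of 26 and fell in 7 (camera, adjusted p = 0.725), with the regulator of glycolysis PFKFB3 (0.29) and hexokinase HK1 (0.16) higher and the peptide ADM (-0.86) and the glucose transporter SLC2A1 (-0.49) lower. The list's mean log2 level was 0.017 and 0.067 in shPRSS22 replicates 1 and 2 but -0.171 in replicate 3, against 0.066, 0.074 and -0.053 in shCtrl. With the replicate number as a block camera called the list lower (adjusted p = 0.0341). ADM lost its call without shCtrl replicate 1 (adjusted p = 0.114), shCtrl replicate 2 (0.110), shPRSS22 replicate 1 (0.0738) or shPRSS22 replicate 2 (0.0751). SLC2A1 lost its call without shCtrl replicate 1 (0.101), shCtrl replicate 2 (0.0904), shCtrl replicate 3 (0.0547) or shPRSS22 replicate 1 (0.0842). Nuclear oxidative phosphorylation genes rose in 8 of 30 and fell in 9 (0.922), with SDHB (0.29) and NDUFA4 (0.24) higher and NDUFB10 (-0.31) and NDUFV1 (-0.26) lower. The counts for both lists were the same adjusted over the list alone.

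Of the remaining lists too few members were tested for camera. Intestinal differentiation genes had 4 tested members, of which KRT20, a keratin of differentiated intestinal cells, and CA2, carbonic anhydrase 2 (0.29), rose. KRT20, with a log2 fold change of 1.29, stood at 3.41 CPM in shPRSS22 replicate 1, 1.51 and 1.57 CPM in replicates 2 and 3 and 0.868, 0.990 and 0.793 CPM in shCtrl, and without shPRSS22 replicate 1 its log2 fold change was 0.795 (adjusted p = 0.0501). That library also held most reads of intestinal genes too low to test: FABP1 had 13 counts there and SLC26A3 had 16, with 0 in each of the other 5 libraries. Over the 16 members of the list below 0.5 CPM in shCtrl with any count, shPRSS22 replicate 1 held 115 of 194 counts. Without this library 2371 genes were higher and 2271 lower. Histone genes rose in 2 of 4 tested members, H2BC5 (0.51) and H1-2 (0.35), where poly(A) selection recovers few replication-dependent histone mRNAs. H1-2 lost its call without shCtrl replicate 2 (adjusted p = 0.0502) or shCtrl replicate 3 (0.0870). Of 3 tested markers of fibroblasts, immune and endothelial cells, CD68 rose (0.24) and COL1A1 (0.08) and VWF (0.34) did not pass. CD68 lost its call without shCtrl replicate 1 (0.0693), shCtrl replicate 3 (0.0993), shPRSS22 replicate 1 (0.0876) or shPRSS22 replicate 2 (0.140). The counts for these lists were the same adjusted over the list alone.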

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

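Of these settings, the lists without shared members were chosen after seeing the data, and that setting called 5 lists higher and 4 lower. PRSS22 stayed lower under every setting, and no gene called here was called in the opposite direction in any of them. The median log2 fold change of all tested genes stayed between -0.010 and -0.0019. Scaling, filter and limma-voom left between 2511 and 2683 genes higher and between 2487 and 2596 lower, and leaving out 1 library left 2161 to 2484 and 2079 to 2271. DESeq2 called fewer, 1760 higher and 1637 lower; the cause was not tested. Changes of at least 2-fold rose to 160 higher and 64 lower with no filter, which adds low genes. They fell to 64 and 23 at a mean CPM of at least 1, which removes low genes, and to 64 and 20 with DESeq2. Those lower ranged from 29 to 53 when 1 library was left out, with 53 without shPRSS22 replicate 1. With an estimated correlation 3 lists were higher and 1 lower; fry called 5 and 3. Fry did not call mitosis (adjusted p = 0.364) or ribosomal protein genes (0.246) and called YAP/TEAD genes higher (0.0412). Lists not called changed direction in 9 tests, all still over the threshold. With the replicate number as a block, 2782 genes were higher and 2747 lower, Wnt targets had an adjusted p of 0.0544 and hypoxia genes one of 0.0341. Same-numbered libraries had deviations correlated across genes at 0.019, 0.033 and 0.091, and not every library correlated best with its own number. The numbers were therefore not taken to pair the samples in the main test. This correlation over all genes does not exclude an effect of replicate number on some genes. ADM stood at 78.0, 77.1 and 60.8 CPM in shCtrl replicates 1 to 3 and 44.7, 44.4 and 29.5 CPM in shPRSS22. Mean levels of the mitosis, DNA replication and hypoxia lists were also lowest in replicate 3 of both groups. Ribosomal protein genes were instead lowest in shCtrl replicate 1 and shPRSS22 replicate 3. Whether the samples were paired stays open. Among 84 named genes under 13 settings, 40 of 1092 values lost their call, in 11 genes, and 0 reversed; DESeq2 ended the calls of AURKB, FOSB, FN1, ZEB1, IL1A, TNFAIP2, H1-2 and CD68, limma-voom that of ZEB1 and no filter that of ADM. Depth limits genes near 1 CPM, about 15 counts per library.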

Other observations

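The tests of the 6 lists in the next 2 paragraphs, of 7-base words as a source of most lower genes and of markers of intestinal and plasma cells were chosen after the main results were seen. The p-values of the added lists were adjusted over those lists alone. They describe the size of a pattern already seen and are not tests of a question set beforehand.

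Lysosomal genes fell as a list. Of 35 tested genes for lysosomal enzymes and membrane proteins 22 fell and 2 rose, or 23 and 2 adjusted over the list alone, with a median log2 fold change of -0.20 (camera over the 5 added lists large enough, adjusted p = 6.93e-10; 0.0248 with an estimated correlation). The sulfatase ARSG (-0.84), the carboxypeptidase PRCP (-0.73), the mannosidase MANBA (-0.52) and HEXA, a hexosaminidase subunit (-0.49), fell, while GLA, alpha-galactosidase, rose by 0.36. Autophagy genes went the other way: 20 of 27 rose and 1 fell, or 21 and 1 adjusted over the list alone (median 0.20; adjusted p = 6.93e-10; 0.0248 with an estimated correlation). The receptor SQSTM1, which also binds KEAP1, rose by 0.73, MAP1LC3B by 0.59 and the kinase ULK1 by 0.36, and ULK2 fell (-0.27). The difference between the lists was not tested itself.

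Cytosolic aminoacyl-tRNA synthetase genes rose in 11 of 20 and fell in 2, or 11 and 4 adjusted over the list alone (median 0.09; adjusted p = 2.18e-04; 0.0248 with an estimated correlation), led by CARS1 (0.37), WARS1 (0.35) and TARS1 (0.30); the ATF4 list shares AARS1, GARS1, SARS1 and WARS1. Genes of the COPII coat and the endoplasmic reticulum translocon rose in 12 of 22 and fell in 0, or 13 and 0 adjusted over the list alone (median 0.12; adjusted p = 1.34e-06; adjusted p = 0.0815 with an estimated correlation), with SERP1 at 0.48 and SEC24A at 0.43. Proteasome subunits rose in 14 of 31 and fell in 1, or 15 and 1 adjusted over the list alone (median 0.08; adjusted p = 0.00282; adjusted p = 0.338 with an estimated correlation), with PSMD12 at 0.25. The collagen VI chains parted: COL6A3 rose by 2.02 while COL6A1 (-0.41) and COL6A2 (-0.34) fell.

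The rise of NRF2 targets could in principle follow from a change in the transcripts of NRF2 itself or of its inhibitor KEAP1. KEAP1 was higher, not lower, in shPRSS22 (log2 fold change 0.40, 95% interval 0.29 to 0.52, adjusted p = 1.08e-06), which argues against a lower KEAP1 transcript. NFE2L2, which encodes NRF2, rose by 0.16 (0.096 to 0.23), short of the 0.5 set beforehand for a transcript-level cause. A trend with GC content and transcript length moved the list's median from 0.71 to 0.69 and no member by more than 0.062. The bootstrap interval of the corrected median (0.32 to 1.06) reaches under the bound of 0.35 set beforehand. By that rule such a bias is not excluded. The interval measures the spread among members and not the size of the trend, so the rule cannot decide. The trend itself, at most 0.062 for any member against a median of 0.71, argues against GC content or transcript length as the source of the rise. A contribution of the higher NFE2L2 transcript stays open. So do regulation of NRF2 at the protein level and an effect of hairpin or clone unrelated to PRSS22, neither of which these data test.

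The many small falls might include direct targets of the hairpin through matches of 7 bases in 3' UTRs, as small interfering RNAs cause. The hairpin sequence is not given in the sources used here, so the 7-base words of PRSS22 mRNA were tested, corrected for the length and GC content of the 3' UTR, over 12910 genes. The word with the lowest z of 16233 tested, CCACCAC, does occur in PRSS22 mRNA, but its z of -4.37 did not pass the bound of -4.41 from 100 permutations of the genes, although it passed the bound over the PRSS22 words alone (-4.10), and its genes were shifted by -0.022 on the log2 scale. Words absent from PRSS22 mRNA reached similar sizes, TTTTGAG with a z of -4.29 and GTGTCAC with one of 4.52. The test leaves a weak seed effect open. Such a word was carried by 25.5% of the 2481 lower genes searched and 19.3% of the others, an excess of 6.18 percentage points, too small for direct matches to 1 word to account for most lower genes.

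The reads of intestinal genes in shPRSS22 replicate 1 may come from other intestinal cells or tissue mixed into that library at some step. At least 60% of the counts of 14 genes with 10 or more counts lay in that library, against 1 to 5 such genes in each other library. The 14 genes held 311 counts there, fewer than the 367 that 3 such genes held in shCtrl replicate 1, so the library stood apart by number of genes and not by counts. The 14 included JCHAIN, a chain of secreted antibodies, with 89 counts against 0 or 1 elsewhere, PIGR, the epithelial antibody transporter, with 52 against 2 to 6, and CLCA1, a goblet cell gene, with 22 against 0 or 1. Of the 32 further markers of colon epithelium in the table, 23 had counts and lay below 0.5 CPM in shCtrl, and of these it held 38.6% of 158 counts (exact 95% interval 31.0 to 46.7%, counting error only), above its 16.9% of all counts but short of the 40% set before they were counted. Markers of plasma and B cells gave 25.9% of 108 counts (18.0 to 35.2%), which decides nothing, and the fibroblast, immune and endothelial list 28.4% of 162 counts. The library had 15466647 counts in all, so these are traces, and carried-over RNA, reads assigned from another library and a real rise in those cells all stay open.

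At least 9 interferon-stimulated genes of the list were lower whichever library was left out, and of the 12 members with a mean of at least 5 CPM 9 were lower.

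The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 2603 higher and 2523 lower genes, 95 and 30 of them by at least 2-fold, and the highest other split gave 0 for each; for each of these counts 1 split of 10, the real one, gave as many. At an unadjusted p under 0.05 in edgeR the real split had 6126 genes and the others 117 to 254. Each other split sets libraries of both groups on either side, so the real difference widens the spread within its sides. Few calls follow from that, and these counts do not measure what chance gives. The list counts of those splits also carry part of the real difference. Of lists called at the preset correlation, the real split gave 5 higher and 4 lower, and since the direction of a split is arbitrary, each other split was counted by its larger number of lists in either direction. On that count the highest other split gave 6, 5 of the 10 splits gave at least 5 and 7 gave at least 4, the real one included. The preset correlation is 0.01, whereas the estimated correlation was 0.84 among mitosis genes and 0.76 among ribosomal protein genes. With estimated correlations the real comparison called 3 lists higher and 1 lower. The Wnt and NF-kB lists also lost their calls, at estimated correlations of 0.00038 and -0.060, below the preset value. Their loss therefore does not follow from a higher correlation among members.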
